A study of Mus musculus with 8 samples.

How the data were processed

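Polyadenylated RNA was sequenced from the brains of C57BL/6 mice in 8 libraries, 4 labelled wild type (WT) and 4 labelled Uhrf2 knockout (KO). Per the labels' protocols, RNA was extracted with Trizol, purified on columns and made into libraries with a stranded mRNA kit. The deposited table holds estimated read counts (expected counts) per gene, one column per library, not scaled between libraries. Of all values, 91.5% were whole within 0.001 and the others were fractions. The submitters' processing notes name TopHat2 2.0.9, edgeR and the GRCm38 (mm10) genome build, with no role or order. The counting program and its strand setting are not given in the sources used here, so reads of a gene and of an overlapping or antisense neighbour cannot be told apart.

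The table lists 17613 genes, of which 4 are at 0 in all 8 libraries, and 0 rows name no gene. Library totals ran from 11891350 to 19773921 counts, so that a count of 3 corresponds to between 0.152 and 0.252 CPM, the counts scaled to the size of the library. The locus given for a gene is an interval that 6458 genes (36.7%) share with another gene. Positions were therefore taken from GENCODE M21 on GRCm38, where 17286 of the gene identifiers were found. GC content and length were those of the longest protein-coding transcript of each gene, or of its longest transcript where none is protein-coding. Genes of the mitochondrial genome and Xist were not analysed here.

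Expected counts were rounded to whole numbers. Genes were kept by edgeR's filterByExpr on the group, which left 15902, and library sizes were scaled by TMM. The groups were compared with edgeR 4.0.16 (R 4.3.3) by the robust quasi-likelihood test, with group as the only term and Benjamini-Hochberg adjustment over all tested genes at a threshold of 0.05. Fold changes are those of the libraries labelled KO over those labelled WT, on the log2 scale, and each standard error (SE) was obtained from the fitted coefficient and its F statistic. CPM values are means ± standard deviation (SD) over 4 libraries. The Uhrf2 level was also compared with an exact two-sided permutation test over the 70 ways to choose 4 of 8 libraries. Positions near Uhrf2 were compared with Fisher's exact test, two-sided, for a window of 10 Mb on either side.

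Gene lists were written before the data were examined. They hold known epilepsy genes, activity-regulated genes, DNA methylation machinery, receptors, synaptic vesicle genes, markers of cell types, brain regions and neighbouring tissues, and genes of stress, clock, sex, imprinting and metabolism. Of 36 lists, 35 had at least 3 tested members and were compared with all other tested genes by camera (limma 3.58.1), with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the lists. Camera was repeated with the correlation estimated for each list, and fry was run as a self-contained test. Members past the threshold were counted after adjustment over all genes and again adjusted over the list alone.

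The rule for naming genes was fixed before the data were examined. It takes Uhrf2 and, among genes past the threshold with a mean of at least 1 CPM in 1 group and with no overlap between the groups, the 12 largest rises and the 12 largest falls, leaving out unnamed gene models, pseudogenes and sex-linked genes. It adds the 4 members with the lowest p of each list past the threshold, at most 4 members past the threshold of each other list, and at least 2 members of the epilepsy, activity, DNA methylation, interneuron and sex-linked lists. Some members that the rule takes are not reported here. Genes outside this rule were named after their values were seen, among them the remaining members past the threshold of a list.

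Principal components and Pearson correlations used log2 CPM with a prior count of 2. Pairs of libraries within a group differed by more than sampling noise, with a chi-square per degree of freedom of 2.46 to 5.04, so all 8 were kept as separate samples. The labels do not say whether the libraries come from separate animals. The p-values are therefore set against the spread between these libraries, which need not be that between animals. The common coefficient of variation of the fit, beyond counting noise, was 5.38%. The tests were checked on simulated counts for the KO against WT comparison, drawn for 15902 genes of which 200 were changed. The changed genes were drawn from those with an average log2 CPM above 2, so recovery at lower levels was not simulated. Of 50 genes at each size, 64% were recovered at 1.25-fold, 92% at 1.5-fold, 98% at 2-fold and 100% at 3-fold, and 12 unchanged genes were called. With no change simulated, 3 genes were called. A GC trend added to simulated unchanged libraries gave 929 calls, and 0 once the trend was removed.

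Alternatives were median-ratio and upper-quartile scaling, no filter and a filter of more than 1 CPM in at least 4 libraries, DESeq2 1.42.0, limma-voom with and without quality weights, the replicate number as a block, each library left out in turn, sex-linked genes left out, an adjusted p under 0.1, and a test against a fold of 1.2. Added after the data were examined were a fit with each library's trend on GC content and transcript length removed (loess span 0.5), and a fit without both libraries numbered 1.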

Results

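The series measured gene expression in whole brain of C57BL/6 mice to compare wild type with the knockout of Uhrf2, which encodes a nuclear protein that binds modified cytosine in DNA. Its title links the gene to local 5-methylcytosine and to spontaneous seizures. There were 4 libraries labelled WT and 4 labelled KO. The WT libraries held 11891350, 16196375, 19773921 and 15449545 counts for replicates 1 to 4, and the KO libraries held 13550420, 15585100, 19065173 and 15155135.

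Uhrf2 was read first, because the targeted gene checks the labels. Its level was 55.4 ± 5.22 CPM (SD, n = 4) in the libraries labelled WT and 88.8 ± 2.23 CPM (SD, n = 4) in the libraries labelled KO, 1.60-fold higher in the latter. The lowest KO library, at 86.4 CPM, lay above the highest WT library, at 58.9 CPM. The log2 fold change was 0.68 (SE 0.06, adjusted p = 5.45e-06 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The exact two-sided permutation test gave p = 0.0286, the smallest that 4 against 4 can give. Uhrf2 (ENSMUSG00000024817) lies on chromosome 19 from 30030513 to 30093722 on GRCm38. This direction goes against the label of a knockout. Counts per gene do not separate reads inside the deleted part from reads outside it, so the groups are named by their labels throughout, and every direction below rests on those labels.

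**Figure D1:**
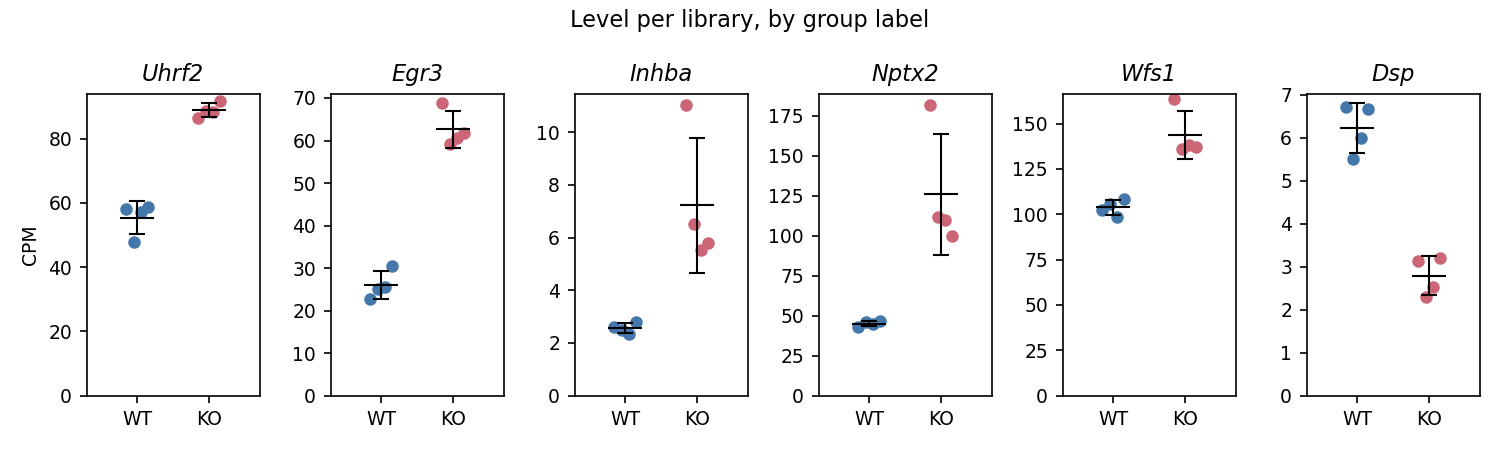
CPM of 6 genes in each library, with WT and KO as labelled on the horizontal axis; points are libraries and bars are the mean ± SD (n = 4). Uhrf2, Egr3, Inhba, Nptx2 and Wfs1 lay higher in every library labelled KO and Dsp lay lower in every one, with Nptx2 at 182 CPM in KO replicate 1.

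Across the transcriptome, genes induced by neuronal firing were among the largest rises in the libraries labelled KO. Egr3, an activity-induced transcription factor, rose from 26.0 ± 3.28 to 62.6 ± 4.26 CPM (SD, n = 4), 2.40-fold. Nptx2, a secreted protein that clusters glutamate receptors, rose from 45.1 ± 1.56 to 126 ± 37.8 CPM, and Inhba, the activin beta A subunit, rose from 2.56 ± 0.18 to 7.22 ± 2.57 CPM. The largest fall was that of Dsp, which encodes desmoplakin and marks the dentate gyrus, from 6.23 ± 0.58 to 2.79 ± 0.45 CPM. Of 15902 tested genes, 228 changed at an adjusted p under 0.05 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), 182 higher and 46 lower in the libraries labelled KO. The changes were small, with a median of 1.27-fold among the higher genes and 1.23-fold among the lower ones. In all, 37 of the higher and 3 of the lower genes passed 1.5-fold, and 12 and 1 passed 2-fold. The groups did not overlap in 225 of the 228, and in 7.67% of all tested genes, where chance gives 2.86%. Tested against a fold of 1.2, 21 genes were higher and 1 was lower. The number of changed genes was 110 without WT replicate 3, 130 without KO replicate 3 and 146 without KO replicate 4, but 324 without KO replicate 2. The lower genes ran from 14 without WT replicate 3 to 77 without KO replicate 2.

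**Figure D2:**
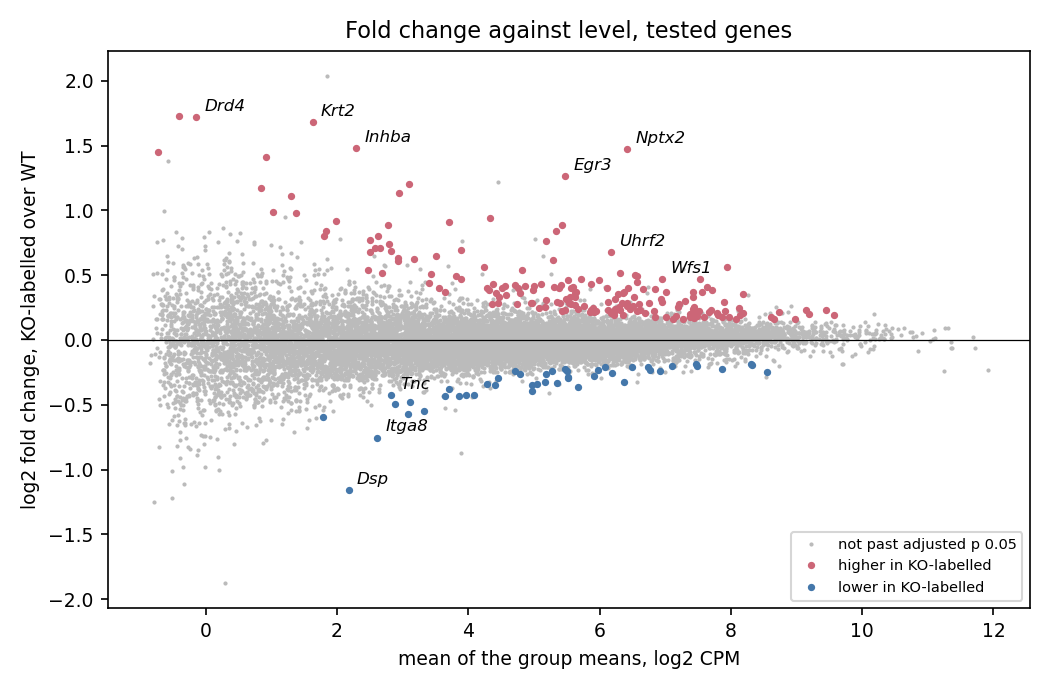
Log2 fold change of libraries labelled KO over WT (vertical axis) against the log2 of the mean CPM of both groups (horizontal axis) for the 15902 tested genes. Coloured points are the 182 higher and 46 lower genes past an adjusted p of 0.05, and 10 of these are named.

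The other genes among the 12 largest rises had low levels in both groups. Drd4, a dopamine receptor, had a log2 fold change of 1.72 (SE 0.34) but a mean of 0.414 ± 0.262 CPM in WT and 1.37 ± 0.243 CPM in KO libraries. Krt2, a keratin, rose by 1.68 (SE 0.28), Fgf3, a fibroblast growth factor, by 1.41 (SE 0.20), and Cenpa, the centromeric histone variant, by 1.17 (SE 0.19). Blnk, an adaptor of B cell receptor signalling, rose from 4.79 ± 0.97 to 10.6 ± 0.68 CPM (SD, n = 4), and Fndc9 from 5.08 ± 0.68 to 11.99 ± 3.92 CPM. Rrad, Agmat and Aim1l rose by 1.11 (SE 0.21), 0.99 (SE 0.19) and 0.98 (SE 0.17) on the log2 scale. Drd4 missed the threshold without WT replicate 3 (adjusted p = 0.0682), as did Agmat (0.0592). Fndc9 missed it without any 1 of the 4 WT libraries, KO replicate 2 or KO replicate 4, at an adjusted p of up to 0.116, and Nptx2 without any 1 of the 4 WT libraries, KO replicate 2 or KO replicate 3, at up to 0.128. Nptx2 also missed it with the replicate number as a block (adjusted p = 0.0894), at a log2 fold change of 1.43.

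The remaining large falls in the libraries labelled KO were of about 1.31- to 1.69-fold. The integrin subunit Itga8 fell from 7.73 ± 0.69 to 4.51 ± 0.84 CPM (SD, n = 4) and Itga4 from 19.5 ± 1.59 to 14.5 ± 0.71 CPM. The cadherin Fat4 fell from 16.8 ± 1.19 to 12.4 ± 2.22 CPM, and tenascin C, Tnc, from 8.13 ± 0.48 to 6.07 ± 0.36 CPM. Fgf10, a growth factor, fell by 0.49 (SE 0.10) on the log2 scale, Fam84b by 0.55 (SE 0.09), Palmd by 0.43 (SE 0.09) and B3galt2, a galactosyltransferase, by 0.39 (SE 0.09). Hps1, a gene of lysosome-related organelles, fell by 0.42 (SE 0.09), BC030499 by 0.57 (SE 0.13) and Ifi203, an interferon-induced gene, by 0.59 (SE 0.14). Dsp, Itga8, Itga4 and Fam84b passed the threshold without any 1 library. Tnc missed it without each of the 8 libraries (adjusted p from 0.0582 to 0.173). Fat4 missed it in all but 1 of the 8 fits, that without KO replicate 4, and B3galt2 in all but the fit without WT replicate 3, at up to 0.132 and 0.101. Ifi203 missed it in 6 of these fits, BC030499 in 5 and Hps1 and Palmd in 3 each, with adjusted p of up to 0.178, 0.184, 0.0786 and 0.0743. Fgf10 missed it without WT replicate 3 (0.07).

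The list of activity-regulated genes ranked upward in the libraries labelled KO by camera with the preset correlation (adjusted p = 2.16e-07) but did not pass with an estimated one (adjusted p = 0.653). Of its 48 tested members, 7 rose, 0 fell and 41 did not pass, with 16 rising when adjusted over the list alone. In all, 27 of the 48 had a positive log2 fold change, with a median of 0.038 and a mean of 0.23. Besides Egr3, Inhba and Nptx2, the members that rose were Gadd45b, a stress- and activity-induced gene tied to DNA demethylation, from 8.98 ± 1.51 to 17.0 ± 2.89 CPM (SD, n = 4), Vgf, a neuropeptide precursor, from 181 ± 18.4 to 237 ± 5.75 CPM, Baz1a from 4.16 ± 1.22 to 7.13 ± 0.64 CPM, and Rheb, from 107 ± 2.02 to 121 ± 5.09 CPM. Vgf missed the threshold with GC content and length trends removed (adjusted p = 0.0528), where its log2 fold change went from 0.39 (SE 0.06) to 0.34 (SE 0.07). Of the other members, these were chosen after their values were seen. Fosb stood at 12.8 ± 3.09 and 30.7 ± 9.39 CPM in WT and KO libraries (adjusted p = 0.11), Bdnf at 27.3 ± 4.17 and 43.0 ± 10.9 CPM (adjusted p = 0.233) and Homer1 at 126 ± 23.8 and 184 ± 33.8 CPM (adjusted p = 0.281). The rapid genes Fos, Npas4 and Arc had log2 fold changes of -0.25 (SE 0.23), -0.54 (SE 0.30) and 0.003 (SE 0.35).

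**Figure D3:**
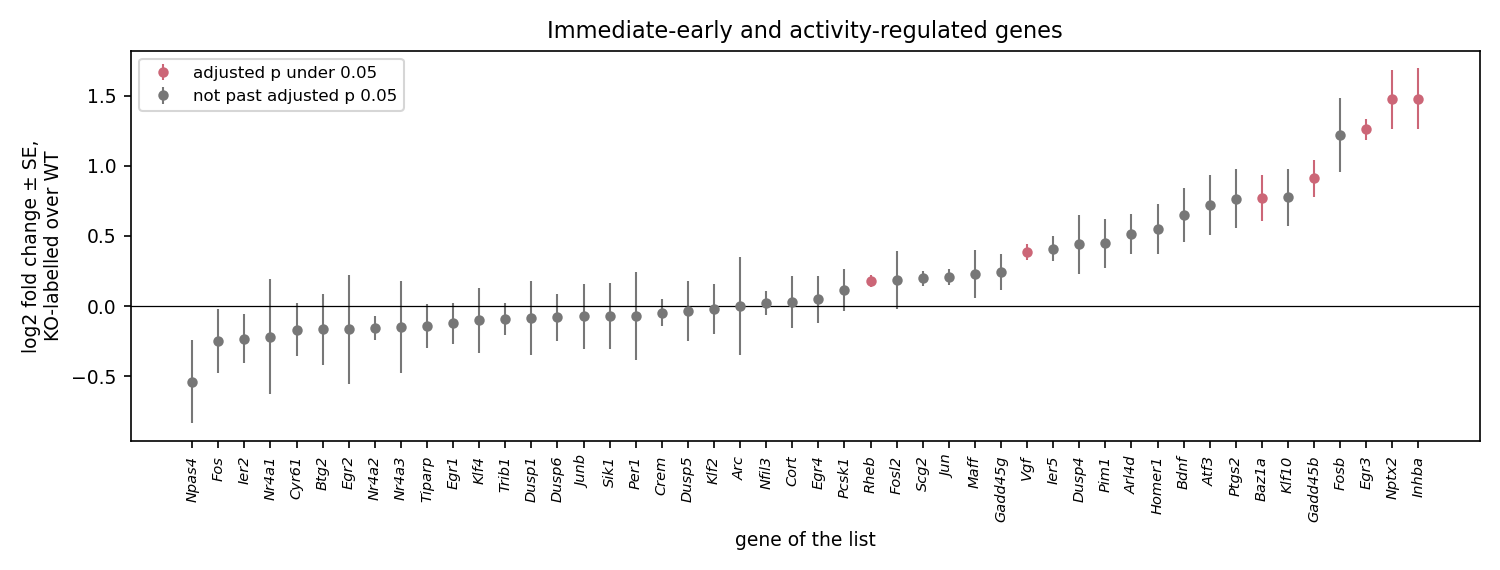
Log2 fold change ± SE of libraries labelled KO over WT (vertical axis) for each of the 48 tested activity-regulated genes, ordered by value (horizontal axis). The 7 coloured genes passed an adjusted p of 0.05 and lie between 0.18 and 1.48.

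The stress and handling list had the lowest p by camera with the preset correlation (adjusted p = 6.26e-09) but did not pass with an estimated one (adjusted p = 0.609). Of 30 members, 2 rose, 0 fell and 28 did not pass, with 9 rising when adjusted over the list alone, at a median log2 fold change of 0.13. Fkbp5, a glucocorticoid-induced chaperone partner, rose from 38.8 ± 2.98 to 53.2 ± 2.05 CPM (SD, n = 4), and Cdkn1a, the cell cycle inhibitor p21, from 22.9 ± 2.57 to 33.6 ± 4.40 CPM. The heat shock gene Hsph1 stood at 269 ± 33.6 and 342 ± 25.7 CPM (adjusted p = 0.118) and the metallothionein Mt2 at 82.1 ± 6.43 and 97.5 ± 9.70 CPM (adjusted p = 0.111).

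By camera with the preset correlation, striatal markers ranked upward (adjusted p = 4.2e-08) and cerebellar markers downward (adjusted p = 3.53e-05), but neither passed with an estimated correlation (adjusted p = 0.653 and 0.871). Of 26 striatal markers, 4 rose, 0 fell and 22 did not pass, with 9 rising when adjusted over the list alone, at a median log2 fold change of 0.10. These were the opioid precursor Pdyn (27.4 ± 2.96 to 35.8 ± 2.65 CPM, SD, n = 4), the signalling inhibitor Ppp1r1b (222 ± 12.7 to 259 ± 13.7 CPM), the dopamine receptor Drd1a (28.0 ± 2.40 to 33.9 ± 0.91 CPM) and the adenylyl cyclase Adcy5 (255 ± 9.28 to 286 ± 4.25 CPM). Of 31 cerebellar markers, none passed over all genes or over the list alone, 3 had a positive log2 fold change, and the median was -0.12. Its members with the lowest p were Nrk, Svep1, Zic2 and Id4, at log2 fold changes of -0.28 (SE 0.09), -0.43 (SE 0.13), -0.19 (SE 0.07) and -0.12 (SE 0.05). The cerebellar list missed the threshold without KO replicate 4 (camera adjusted p = 0.0859). Pdyn missed it without WT replicate 3 (adjusted p = 0.0652), and Ppp1r1b, Drd1a and Adcy5 in 3, 5 and 6 of the 8 fits without 1 library, at up to 0.0908, 0.153 and 0.141. Without both libraries numbered 1, Pdyn, Ppp1r1b, Drd1a and Adcy5 all missed it (adjusted p = 0.071, 0.053, 0.0653 and 0.11), as did Adcy5 with GC content and length trends removed (0.0663).

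Synaptic vesicle genes and nuclear genes of the respiratory chain ranked upward by camera with the preset correlation (adjusted p = 0.000123 for either list) but did not pass with an estimated one (adjusted p = 0.653 and 0.867). Of 45 vesicle genes, 1 rose, 0 fell and 44 did not pass, with 7 rising when adjusted over the list alone, at a median log2 fold change of 0.044. The member that rose was the vesicle glycoprotein Sv2c, from 32.4 ± 1.66 to 40.2 ± 4.18 CPM (SD, n = 4). Amph and Syn2 had log2 fold changes of 0.15 (SE 0.04) and 0.14 (SE 0.04) and did not pass over all genes. Of 82 respiratory chain genes none passed, over all genes or over the list alone, and 69 had a positive log2 fold change, at a median of 0.046. Its members with the lowest p were Cox5a, Ndufs5, Sdha and Ndufs7, between 0.080 and 0.17 on the log2 scale. Sv2c missed the threshold in 6 of the 8 fits without 1 library, at an adjusted p of up to 0.105.

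Markers of blood vessels and of myelin ranked downward by camera with the preset correlation (adjusted p = 0.00081 and 0.00586) but did not pass with an estimated one (adjusted p = 0.867 and 0.871). Of 32 endothelial and pericyte markers, 1 fell, 0 rose and 31 did not pass, and 1 fell when adjusted over the list alone, at a median log2 fold change of -0.092. The member that fell was the thyroid hormone transporter Slco1c1, from 67.7 ± 4.17 to 57.6 ± 2.75 CPM (SD, n = 4), and it missed the threshold in 6 of the 8 fits without 1 library, at an adjusted p of up to 0.13. Slco1c1 missed it too with GC content and length trends removed (adjusted p = 0.0809). Rgs5, Itm2a and Tek had log2 fold changes of -0.13 (SE 0.04), -0.19 (SE 0.06) and -0.23 (SE 0.08) and did not pass. Of 29 myelin markers none passed, over all genes or over the list alone, at a median of -0.055. Tspan2, Gpr37 and Gjc3 had log2 fold changes between -0.139 and -0.125. Without KO replicate 4 the myelin list missed the threshold (camera adjusted p = 0.169).

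These 8 lists, 5 higher and 3 lower, were the ones that passed camera with the preset correlation. With an estimated correlation 0 of 35 passed, and fry, tested for a shift in 1 direction, gave 0 after adjustment. Fry's mixed p, which counts changes in either direction, was not adjusted over the lists. It ran from 2.48e-08 for the DNA methylation machinery and 1.93e-07 for hippocampal markers to 0.925 for blood. For activity-regulated genes it was 1.95e-05.

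Known epilepsy genes did not pass as a set or singly. Of 75 tested, 0 passed over all genes and 0 adjusted over the list alone, at a median log2 fold change of 0.019 (camera adjusted p = 0.126). Among them, Pcdh19 stood at 39.7 ± 2.25 and 34.3 ± 3.72 CPM in WT and KO libraries (SD, n = 4, adjusted p = 0.193). The set passed camera without WT replicate 4 (adjusted p = 0.0418) and without KO replicate 2 (0.00455). GABA receptor subunits (18 tested, median 0.020, camera adjusted p = 0.433) and glutamate receptor subunits (24 tested, median -0.028, camera adjusted p = 0.433) held no member that passed over all genes or over the list alone, and the former passed camera without KO replicate 2 (0.0474).

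In the DNA methylation machinery, 2 of 41 genes rose, 0 fell and 39 did not pass, with the same count adjusted over the list alone (median 0.013, camera adjusted p = 0.433). They were Gadd45b, already given, and Cxxc5, a protein with a domain that binds unmethylated CpG, from 82.5 ± 3.15 to 99.4 ± 1.47 CPM (SD, n = 4). Lists of genes known to depend on DNA methylation held no member that passed over all genes. These were imprinted genes (47 tested, median 0.029, camera adjusted p = 0.188), germline genes (16 tested, median -0.056, 0.944, with 1 member higher when adjusted over the list alone) and clustered protocadherins (23 tested, median -0.086, 0.107). Imprinted genes passed camera without KO replicate 3 (adjusted p = 0.0339), and protocadherins without WT replicate 3, KO replicate 1 or KO replicate 3 (0.0158, 0.0227 and 0.0473).

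Hippocampal markers split. Of 27 tested, Wfs1, Ociad2, Pitpnm2 and Tyro3 rose, Dsp fell and 22 did not pass, and 6 rose and 4 fell when adjusted over the list alone. The median log2 fold change was -0.039 and the mean -0.067, while camera placed the list upward, at an adjusted p of 0.944. Wfs1, a membrane protein of the endoplasmic reticulum that marks CA1, rose from 104 ± 4.25 to 144 ± 13.1 CPM (SD, n = 4), Ociad2 from 68.9 ± 2.55 to 80.1 ± 3.71 CPM and Pitpnm2 from 234 ± 5.28 to 265 ± 12.6 CPM. Among forebrain excitatory neuron markers, 2 of 29 rose, 0 fell and 27 did not pass, with 4 rising when adjusted over the list alone (median 0.039, camera adjusted p = 0.102). They were the cortical transcription factor Emx1, from 8.94 ± 0.53 to 12.7 ± 0.51 CPM, and the pentraxin Nptx1, from 394 ± 17.5 to 458 ± 12.4 CPM. Of 30 interneuron markers, the neuropeptide gene Npy rose, from 36.6 ± 2.03 to 44.7 ± 2.17 CPM, and 29 did not pass, with 1 rising when adjusted over the list alone (median 0.053, camera adjusted p = 0.0793), and Slc32a1, the vesicular GABA transporter, stood at 136 ± 3.19 and 147 ± 4.18 CPM (adjusted p = 0.241). Npy missed the threshold without KO replicate 3 (adjusted p = 0.0665), and Ociad2 and Pitpnm2 in 5 and 7 of the 8 fits without 1 library, at up to 0.116 and 0.128. The excitatory list passed camera without WT replicate 2 (0.0101) or KO replicate 2 (0.00432) and with quality weights (0.0244), and the interneuron list without WT replicate 1 (0.0338) or KO replicate 2 (0.0114).

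Among glial and immune lists, myelin, given above, was the only one that passed camera with the preset correlation in the fit with all 8 libraries. Astrocyte markers (28 tested, median -0.039, camera adjusted p = 0.0597) held no member past the threshold over all genes and 2 lower ones adjusted over the list alone, and passed camera without WT replicate 1 (0.0384), WT replicate 4 (0.0354), KO replicate 1 (0.00414) or KO replicate 2 (0.0114). The astrocyte list also passed camera, always lower in the libraries labelled KO, with upper-quartile factors (0.0471), quality weights (0.00851), GC content and length trends removed (0.0357) and without both libraries numbered 1 (0.0019). Markers of oligodendrocyte precursors (17 tested, median -0.036, 0.433) and microglia (31 tested, median -0.042, 0.275) held none by either adjustment. Of 37 interferon and inflammatory genes, Serpina3n, an acute-phase protease inhibitor of reactive astrocytes, rose from 16.8 ± 0.46 to 22.3 ± 2.06 CPM (SD, n = 4), also adjusted over the list alone (median 0.038, camera adjusted p = 0.182), and this list passed camera without WT replicate 2 (0.0237) or KO replicate 3 (0.00101). Of 40 genes of Wnt, BMP and retinoic acid signalling, the ligand Wnt10a rose from 5.17 ± 0.35 to 8.67 ± 0.53 CPM and 39 did not pass, with 2 rising when adjusted over the list alone (median -0.040, mean 0.002, camera adjusted p = 0.979).

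Lists of other tissues and regions gave 1 gene. Of 6 tested pituitary genes, Chga, a granin also expressed in neurons, rose from 181 ± 5.08 to 206 ± 9.91 CPM (SD, n = 4), and adjusted over the list alone 2 rose and 1 fell (median 0.079, camera adjusted p = 0.527). Chga missed the threshold in 6 of the 8 fits without 1 library, at an adjusted p of up to 0.127. It also missed it with GC content and length trends removed (0.0595) and without both libraries numbered 1 (0.182). No member passed over all genes or over the list alone among markers of choroid plexus (26 tested, median -0.074, camera adjusted p = 0.188), ependyma (23 tested, median 0.068, 0.701), thalamus, midbrain and hindbrain (29 tested, median 0.023, 0.979), olfactory bulb (21 tested, median 0.037, 0.538), blood (10 tested, median -0.009, 0.979) and meninges (28 tested, median -0.082, 0.333). The same held for hypothalamus (17 tested, median 0.099, 0.182), for ribosomal proteins (81 tested, median 0.020, 0.144), clock genes (22 tested, median 0.016, 0.944) and sex-linked genes (8 tested, median -0.084, 0.339). Eif2s3y and Kdm6a, the sex-linked genes with the lowest p, had log2 fold changes of -0.11 (SE 0.07) and -0.086 (SE 0.06). Choroid plexus passed camera without WT replicate 2 (0.0222) or KO replicate 1 (0.0357), olfactory bulb without WT replicate 3 (0.00756), hypothalamus without KO replicate 3 (0.000679) and meninges without KO replicate 1 (0.00483) or both libraries numbered 1 (0.000614). Ribosomal proteins passed it without WT replicate 2 (0.0222), WT replicate 3 (0.0185) or KO replicate 4 (0.00392).

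The genes around Uhrf2 were examined because a knockout carries the DNA that flanks its target. Of 97 tested genes within 10 Mb of Uhrf2, 0 had changed, against 225 of 15579 elsewhere (1.44%), a difference that did not pass Fisher's exact test (two-sided p = 0.652). Within 20 Mb, 3 of 267 had changed, Blnk, Crtac1 and Hps1. The list of 69 tested flanking genes had a median log2 fold change of -0.013 (camera adjusted p = 0.824), with 0 past the threshold over all genes and 1 higher and 1 lower adjusted over the list alone.

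The libraries of the groups were separated along the first principal component, which held 21.6% of the variance. The second held 19.8%, and on it WT replicate 1 (21) and KO replicate 1 (13.1) stood apart from the other 6 libraries, which lay between -9.0 and -2.5. The median correlation of log2 CPM was 0.993 within either group and between the groups. Without both libraries numbered 1, 162 genes changed, 144 higher and 18 lower.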

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

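The test over other splits of the libraries was chosen before its result was seen. The tests of a mislabelled library, of neighbouring genes, of exchanged labels, of GC content and length, of the libraries numbered 1, of forebrain tissue and time of day, each for called genes and for the whole list, of handling and of a slower stress response were chosen only after the results they bear on were seen.

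In 7 of 146 groups of 4 libraries, 1 library lay far from the other 3, and chance gives about 1 in 20. Uhrf2 stood at 47.7 CPM in WT replicate 2, against 57.2 to 58.9 CPM in the other WT libraries. Nptx2 stood at 182 CPM in KO replicate 1, against 99.6 to 112 CPM in the other KO libraries, and Wfs1 in the same library at 163 CPM, against 136 to 138 CPM. Fgf3 stood at 1.35 CPM in WT replicate 3, against 0.84 to 0.92 CPM. In KO replicate 2, Rrad stood at 4.71 CPM, against 2.80 to 3.01 CPM, and B3galt2 at 24.0 CPM, against 27.7 to 28.3 CPM. On the second principal component, WT replicate 1 had a score of 21, against -6.5 to -2.5 in the other WT libraries.

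The first pattern is that Uhrf2 was higher in every library labelled KO. A single mislabelled library would lie in the range of the other group, and none did, as the pattern itself states. The ratio of the lowest KO to the highest WT level, 1.47, gives the size of this gap and is no separate test. Reads or copy number shared with neighbouring genes are argued against by the 14 tested genes within 1 Mb, whose median log2 fold change was -0.01 (SD 0.10) and whose highest was 0.23 (SE 0.07, Jak2). An exchange of the labels of both groups cannot be told apart from labels that are right, because no other value ties a library to a genotype. Of the sex-linked genes, 0 passed the threshold, but they carry no mark of the Uhrf2 genotype and could not decide this. Also open is that a knockout allele may leave or raise reads over the parts of the gene that are not deleted, which counts per gene do not resolve.

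The second pattern is that 228 genes changed, 79.8% of them higher in the libraries labelled KO. Of the 35 splits of the 8 libraries into 4 and 4, only the real one called 228 genes, and the highest of the others called 16. This argues against chance but cannot exclude it, since the real split can rank no better than 1 in 35. The other splits also mix libraries of both labels, so any difference between the labels lowers their counts. The higher genes had a median GC content of 54.4% and the lower ones 44.3%, against 50.1% elsewhere, but with each library's trend on GC content and length removed, 88.1% of the called genes with a GC value kept their call, and the median size of their change was 0.95 of its value. The libraries numbered 1 are not the only source of the calls, since 162 genes, 144 higher and 18 lower, were called without both. Of these, 140 were among the 228. Without both, the ratio of the median sizes was 0.96. It was taken over the 228 genes, and in 225 of them the groups did not overlap. The ratio could therefore hardly fall, and it does not decide how far these libraries contribute. Genotype, litter, and any other difference that follows the labels may each account for what remains, and none of these was tested.

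The third pattern is that 7 of 48 activity-regulated genes were called, each higher in the libraries labelled KO, at a median log2 fold change of 0.91. Over the list as a whole the median was 0.038, with 27 of the 48 above 0, and camera with an estimated correlation gave an adjusted p of 0.653. The forebrain marker with the highest log2 fold change was Emx1 (0.508, SE 0.086). Egr3, Gadd45b, Inhba and Nptx2 were the 4 called genes that exceeded it by more than 2 SE of the difference, at the least by 0.404. These 4 were picked by the comparison itself, after the values were seen, so it does not decide on more forebrain tissue. The largest change among the 8 clock genes compared was that of Per1 (0.069 in size, SE 0.315), which is also a member of the activity list. The same 4 genes exceeded it by more than 2 SE of the difference, at the least by 0.843. They were again picked by doing so, so a different time of day is not decided either. Of these 4, Nptx2 missed the threshold without any 1 of the 4 WT libraries, KO replicate 2 or KO replicate 3 (adjusted p of up to 0.128). With the replicate number as a block, Nptx2 missed it too (adjusted p = 0.0894). More forebrain tissue and a different time of day both stay open for the 7 called genes and for the list as a whole. The list's median minus that of striatal markers (0.103) was -0.066, and minus the size of the change in Per1 it was -0.032. The 23 of 26 striatal and 18 of 29 excitatory forebrain markers above 0 and the 3 of 31 cerebellar ones go with more forebrain, while hippocampal markers and those of thalamus and hindbrain (16 of 29 above 0) went both ways. Handling at collection stays open. The 9 genes taken as rapid, after the values were seen, were Fos, Junb, Egr1, Arc, Npas4, Nr4a1, Dusp1, Ier2 and Btg2. They had a median of -0.17 and a mean of -0.18 (SE of the mean over libraries 0.21). The mean lies below the bound of 0.2 by less than 2 SE, though by more than 1 SE. These 9 do not stand for the whole activity list. Members left out of them include Egr3 and Fosb, at 1.26 and 1.22, and Egr2 and Nr4a3, at -0.17 and -0.15. A slower stress response stays open too, with a median of 0.13 and a mean of 0.19 in the stress list (SE of the mean over libraries 0.044). With an estimated correlation, camera gave this list an adjusted p of 0.609. Seizures in the hours before collection, which the title of the series brings in, may also raise such genes, and nothing in the labels records them.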

How the results depend on the processing

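The fits without GC content and length trends and without both libraries numbered 1 were chosen after the data were examined. The Uhrf2 log2 fold change kept its direction and its side of the threshold in all fits, with 0.61 to 0.71 when 1 library was left out. Without 1 library, 110 to 324 genes changed, 96 to 247 higher and 14 to 77 lower, and 7 to 13 lists passed, the highest values without KO replicate 2 and the lowest gene counts without WT replicate 3. At an adjusted p under 0.1, 358 genes changed, 93 of them lower. Against a fold of 1.2, 22 changed, 21 higher and 1 lower, by the construction of that test. With quality weights 92 were lower, and without both libraries numbered 1, 18; the cause was not tested. DESeq2 called 311 genes, 220 of them shared, and removing the trends gave 305, with 201 shared. With an estimated correlation 0 lists passed, and 0 by fry for a shift in 1 direction. Of 44 named genes past the threshold, 22 passed without any 1 library, and 0 named genes turned direction. DESeq2 ended the call of 2 (Ifi203, Tnc) and gave no adjusted p for 4 others (Drd4, Fgf3, Cenpa, Agmat), and limma-voom ended that of Fndc9, with and without quality weights. Removing the trends ended 5 (Vgf, Slco1c1, Adcy5, Chga, Ifi203), at an adjusted p of up to 0.0809, as their changes became smaller and, for Vgf, Slco1c1 and Ifi203, their SE larger. Without both libraries numbered 1, 15 calls ended, at up to 0.182 (Agmat, Ifi203, BC030499, Fgf10, Fat4, Palmd, Tnc, B3galt2, Sv2c, Pdyn, Ppp1r1b, Drd1a, Adcy5, Chga, Ociad2).

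With the replicate number as a block, 495 genes changed, 347 higher and 148 lower, 227 of them shared with the fit without it. Nptx2 missed the threshold (adjusted p = 0.0894), and astrocyte markers passed camera (0.0485). The labels do not say what the numbers mark, so the libraries were not taken as pairs. Deviations of same-numbered libraries correlated at 0.21, 0.08, 0.02 and 0.07. WT replicates 1, 2 and 4 and KO replicates 1 and 4 correlated best with their own number, and WT replicate 3 and KO replicates 2 and 3 with another.

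Of the 27 lists that did not pass, 11 turned direction under some alternative, giving 40 turned values, 0 of them past the threshold; the cause was not tested. Their camera adjusted p were 0.902 with no filter and 0.976 with the stricter one (blood), 0.645 and 0.874 with quality weights (thalamus and hindbrain, Wnt), 0.760 and 0.971 with the block (the same lists), and 0.992 by fry (thalamus and hindbrain). With trends removed they were 0.944, 0.922, 0.808 and 0.841 (thalamus and hindbrain, germline, flank of Uhrf2, Wnt), and without both libraries numbered 1 they were 0.663, 0.770 and 0.449 (thalamus and hindbrain, germline, Wnt). Without 1 library, in either direction, the camera adjusted p ran from 0.27 to 0.952 for blood, 0.131 to 0.981 for clock, 0.376 to 0.919 for ependyma, 0.54 to 0.981 for germline, 0.758 to 0.981 for hippocampus, 0.238 to 0.994 for thalamus and hindbrain, 0.673 to 0.967 for Wnt and 0.311 to 0.981 for the flank of Uhrf2. It ran from 0.00101 to 0.967 for interferon genes, 0.00483 to 0.804 for meninges and 0.00756 to 0.786 for olfactory bulb, with the low values in the direction of the fit with all 8 libraries.

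The fit with Xist as a covariate was not run, since Xist was not analysed here, and camera was not run on DESeq2. At these depths, 64% of the smallest simulated changes were recovered, so that small changes are often missed. Genes at lower levels than those simulated as changed were not covered.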

Other observations

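Families of related genes, chosen only after the changed genes were seen, were tested with camera on the same data, so their p-values are descriptions. Of 7 tested genes of the Nogo receptor and LINGO families, 4 rose in the libraries labelled KO and 3 did not pass. The latter were Rtn4r, Lingo2 and Lingo4, at log2 fold changes of 0.16 (SE 0.07), 0.085 (SE 0.09) and -0.002 (SE 0.16). Lingo1 rose from 198 ± 12.7 to 293 ± 17.8 CPM (SD, n = 4), Rtn4rl1 from 65.4 ± 4.95 to 93.7 ± 2.46 CPM, Rtn4rl2 from 13.8 ± 2.45 to 26.5 ± 1.35 CPM and Lingo3 from 43.6 ± 1.85 to 56.3 ± 2.22 CPM. The family's median log2 fold change was 0.37 (camera p = 1.6e-11, p = 0.00367 with an estimated correlation), and 0.34 with GC content and length trends removed. All 3 neuronal pentraxin genes rose, Nptxr from 645 ± 29.8 to 756 ± 33.1 CPM beside Nptx1 and Nptx2. Of 12 granins and neuropeptide precursors, 5 rose and 7 did not pass, at a median of 0.17 (camera p = 7.36e-10, p = 0.00455 with an estimated correlation), and 0.154 with the trends removed (p = 0.00955 with an estimated correlation), where 3 of the 12 passed.

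Of 23 genes of SR splicing factors and their partners, 4 fell in the libraries labelled KO, 0 rose and 19 did not pass, while 21 had a log2 fold change below 0. Sfrs18 fell from 406 ± 19.3 to 342 ± 14.1 CPM (SD, n = 4), Srsf2 from 191 ± 2.02 to 167 ± 6.91 CPM, Ccnl1 from 72.8 ± 1.16 to 63.0 ± 3.20 CPM and Srsf5 from 336 ± 11.1 to 295 ± 19.3 CPM. The median was -0.12 (camera p = 1.03e-09, p = 0.0374 with an estimated correlation), and -0.11 with the trends removed (p = 0.0988 with an estimated correlation).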
